A study of Mus musculus with 12 samples.

How the data were processed

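Total RNA of 12 colonies was amplified with a whole transcriptome kit, labelled with Cy3 and hybridised to 1-colour Agilent whole mouse genome arrays, per the labels' protocols. The files were the scanner output of each array, extracted by the authors with Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09, per the file headers. Each spot's processed signal, background-subtracted and on a linear intensity scale, is the authors' deposited unit. A deposited table of the same arrays holds the authors' processed values, which lie on a log2 scale. Their column medians were 7.21 to 7.24 and their correlation with the log2 spot median was 0.992 to 1.00 on each array, so scale and direction follow from the data. The method that brought the columns to a common distribution is not given in the sources used here. It served as an alternative. The file headers name build mm9, which was not used for coordinates.

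Groups and replicate numbers were taken from the titles of the samples. Each genotype had 4 arrays, each of a single colony, and the replicates are single colonies in every comparison. Arrays lay on 5 slides, each scanned once. Slide 1 held wild-type replicates 1 and 4 and Bmi1 null replicates 1 and 4. Slide 2 held 1 array of each genotype, slide 3 held 1 Bmi1 null and 2 double null arrays, and slides 4 and 5 held 1 array each. Each array had 45018 spots, of which 43379 were not controls, and 0 were saturated. Control spots and spots marked as outliers by the scanner software were left out, the latter as missing values. They were replaced by the group mean only for the gene list tests.

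The processed signal was log2-transformed and the array's 75th percentile was subtracted. Probes well above background, by the scanner software's own test, on at least 3 of 4 arrays of at least 1 genotype were kept, 39338 in all. Spots of 1 probe were averaged. Of several probes of a gene, the one with the highest mean over the 12 arrays stood for the gene, and the text says where the probes of a named gene disagreed in sign. Names came from accessions matched without versions to a RefSeq table of assembly GRCm38.p6: of 41174 probes 24844 had 1 symbol, 0 several and 16330 none, and the last kept the accession or name of the array design. In all 17178 genes had a symbol, and 31064 genes were tested.

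All 12 arrays entered 1 linear model with a mean per genotype (limma 3.58.1 in R 4.3.3, lmFit and eBayes, 9 residual degrees of freedom). The 3 contrasts were Bmi1 null against wild type, double null against wild type and double null against Bmi1 null. P-values were adjusted by Benjamini and Hochberg's method over the genes of a contrast, and a gene was called at an adjusted p under 0.05. A gene not well above background on every array of 1 genotype has only a bound there. Its change is given as at least N-fold, the mean of the brighter genotype against the mean, over the dimmer genotype's arrays, of the higher of its own value and the lowest signal well above background on that array. No fold is given where that ratio was under 1 or both genotypes were below background. These bounds hold for the background-subtracted signal of the main fit, and the authors' table gave smaller folds for some genes.

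The 26 gene lists were fixed before the data were examined, as were the tests, the comparisons, the alternatives and the rule for naming genes: Hox genes, Hox cofactors, other developmental transcription factors, cyclin-dependent kinase inhibitors, Polycomb subunits, p53 targets, S phase genes, G2/M phase genes, dental epithelial stem cell markers, epithelial markers, ameloblast markers, squamous differentiation genes, mesenchymal and fibroblast markers, immune cell markers, endothelial markers, glial, neural and melanocyte markers, senescence-associated secreted factors, interferon-stimulated genes, Hedgehog, FGF, Wnt, Notch, and BMP and activin pathway genes, imprinted growth genes, immediate early and stress genes, and sex-linked genes. Some genes stand in more than 1 list. Lists were tested with camera, a two-sided competitive test against all other genes, at a preset correlation of 0.01, again with an estimated correlation, and with fry. Adjustment covered all lists and the 3 contrasts. With an estimated correlation 0 lists passed the threshold in any contrast, the smallest adjusted p being 0.060. Median, mean and test of a list differed in sign in 9 lists of each contrast against wild type and in 7 of the contrast between the mutants, and none of these was called.

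The rule named Bmi1 and Cdkn2a always. It then took, among genes with an adjusted p under 0.05, an absolute log2 fold change of at least 1 and no overlap between the 4 arrays of one genotype and the 4 of the other, the 8 with the largest rise and the 8 with the largest fall, leaving out names that are only accessions, clones or Gm or Rik identifiers. From each list it took up to 3 called members with the largest absolute change, and it allowed any Hox gene. It gave 123, 123 and 104 genes in the 3 contrasts. The text names fewer of them, and that subset was picked after the values had been seen; 1 gene of the rule is not reported here. Genes near the targeted loci, within 20 Mb, were set against all other tested genes with a known chromosome. Overlaps between comparisons that share arrays are given with 100 simulations of unchanged groups, with the overlap of independent lists, and with the shared arrays split.

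The alternatives, changed 1 at a time, were normexp background correction with an offset of 50, quantile normalization, median scaling, no filter or a filter on all 12 arrays, a floor at the lowest signal well above background, the mean or every probe of a gene, only the 2 genotypes compared, an intensity trend, array weights, replicate number or slide as a block, the authors' table, a fold threshold, and leaving out each array. Normexp was to use the mean spot signal and used the median spot signal, since the columns read here hold the latter. The slide as a random block and the count on autosomes were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the rest.

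The procedure was tested on simulated data with a known set of changed genes at the spread of the real ones. In a simulated Bmi1 null against wild-type contrast over 31064 genes, 1.49% of genes changed 1.5-fold, 13.7% of those changed 2-fold and 73.3% of those changed 4-fold were recovered, with 3 of 30864 unchanged genes called. For double null against Bmi1 null the shares were 0%, 14.1% and 64.4%, with 2 unchanged genes called. A list of 40 genes shifted by 0.5 passed camera's test in both simulations, and 4 and 1 of 199 unchanged lists had p under 0.05. The simulated noise was independent between genes, whereas the estimated correlation within real lists reached 0.45 (squamous genes), so these rates do not carry over to correlated lists. Far fewer genes were changed than the 25935 called in the real Bmi1 null against wild-type contrast. The recovered shares therefore do not describe that contrast.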

Results

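Gene expression was measured in 12 colonies of mouse dental epithelial stem cells, each grown in culture from cells of the labial cervical loop, the niche at the base of the continuously growing incisor. The colonies fell into 3 genotypes with 4 single-colony replicates each: wild type, Bmi1 null, and double null for Bmi1 and the Ink4a/Arf locus. Each colony was hybridised to 1 Agilent whole mouse genome array in 1 colour, and the mice were of mixed genetic background. After filtering, 31064 genes were tested. The median signal of an array was 109 to 210 in wild type, 82.8 to 190 in Bmi1 null and 63.2 to 157 in double null colonies, over a local background of 17 to 23. The number of arrays limits the precision. The number of animals behind the colonies is not given in the sources used here, so the p-values measure the spread between colonies.

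The targeted genes were examined first. Bmi1, a subunit of Polycomb repressive complex PRC1, had 2 probes. The brighter one gave a level of -0.27 ± 0.46 (SD, n = 4, log2 signal minus the array's 75th percentile) in wild type, -2.35 ± 0.15 in Bmi1 null and -2.53 ± 0.20 in double null colonies, all well above background. The dimmer probe was well above background on all 4 wild-type arrays and on 1 of 4 arrays of each mutant. Bmi1 fell by 2.08 ± 0.23 (SE) on the log2 scale in Bmi1 null colonies (limma adjusted p = 4.01e-06) and by 2.26 ± 0.23 in double null colonies (adjusted p = 1.79e-06), while the change between the mutants was not called (-0.18 ± 0.23, adjusted p = 0.719; 0.17 with the dimmer probe). The dimmer probe fell by 4.12 ± 0.35 in Bmi1 null and 3.95 ± 0.35 in double null colonies against wild type, in a fit of every probe. Relative to the median of all genes, which was itself lower against wild type, Bmi1 fell by 0.85 and 0.86 with the brighter probe. Cdkn2a, the gene of the Ink4a/Arf locus that encodes the cyclin-dependent kinase inhibitor Ink4a and the p53 activator Arf, had 1 probe. It was well above background on 4 of 4 Bmi1 null arrays and on 0 of 4 arrays of each other genotype. Cdkn2a was at least 1.80-fold higher in Bmi1 null than in wild-type colonies (adjusted p = 1.12e-05) and at least 2.57-fold lower in double null than in Bmi1 null colonies (adjusted p = 6.28e-06). With normexp background correction both calls ended: against wild type the change turned sign (0.75 relative to the median of all genes, beside 2.80 in the main fit), and between the mutants it was -0.049. In the authors' table the Cdkn2a change between the mutants was -0.90 on the log2 scale, called but smaller than the 2.57-fold bound. No fold is given between double null and wild type, where the probe was not well above background in either. The position of these probes against the deleted exons was not analysed here, so their signal is a partial check of the labels.

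**Figure D1:**
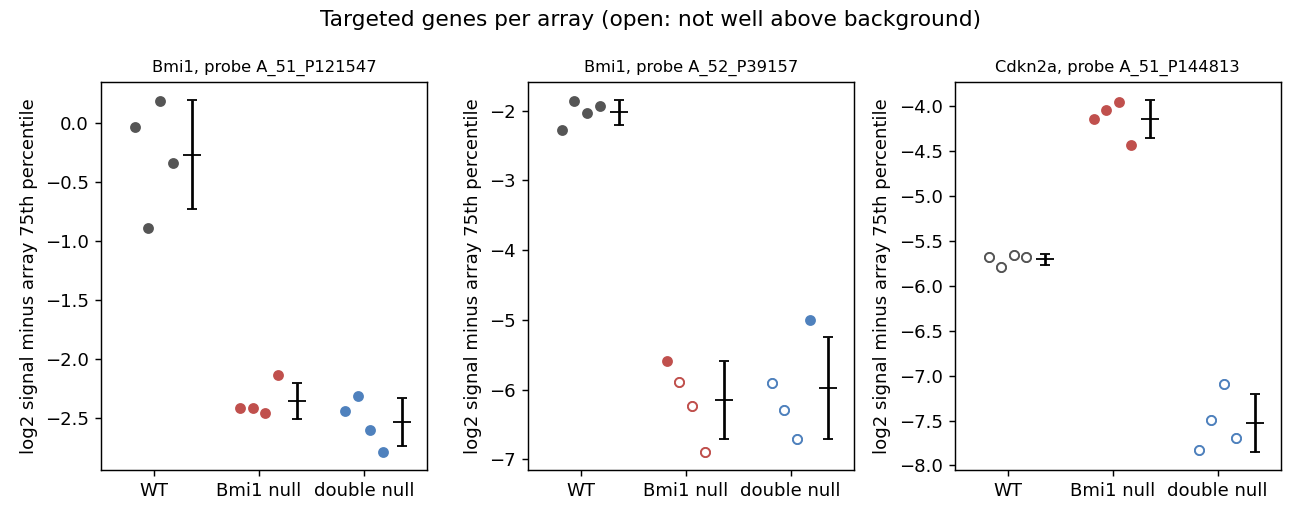
Level of each probe of Bmi1 and Cdkn2a on every array (vertical axis: log2 signal minus the array's 75th percentile; points: single colonies, open where not well above background; bars: mean and SD of 4 colonies). The brighter Bmi1 probe lies at -0.27 in wild type against -2.35 and -2.53 in the mutants, and Cdkn2a is well above background in Bmi1 null colonies only.

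The wild-type arrays had a narrower range of signals than the mutant arrays. The interquartile range of the log2 signal was 2.56 ± 0.06 (SD, n = 4) in wild type, 4.52 ± 0.18 in Bmi1 null and 4.66 ± 0.42 in double null colonies, and 94.6% ± 2.70, 82.5% ± 3.50 and 80.1% ± 5.56 of spots were well above background. Olfactory receptor genes, which serve odour detection in the nose, were well above background at 98.4% ± 1.34 in wild type, against 64.7% ± 8.65 in Bmi1 null and 58.5% ± 10.1 in double null colonies. Ribosomal protein genes, needed in every cell, lay at a median log2 of 3.81 ± 0.28 above the array's own median in wild type, 6.77 ± 0.30 in Bmi1 null and 7.0 ± 0.27 in double null colonies. Both families were chosen after the data had been seen. Spearman correlations of array pairs over genes, which are not independent replicates, were 0.67 to 0.77 between wild type and either mutant and 0.94 to 0.97 between the mutants.

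**Figure D2:**
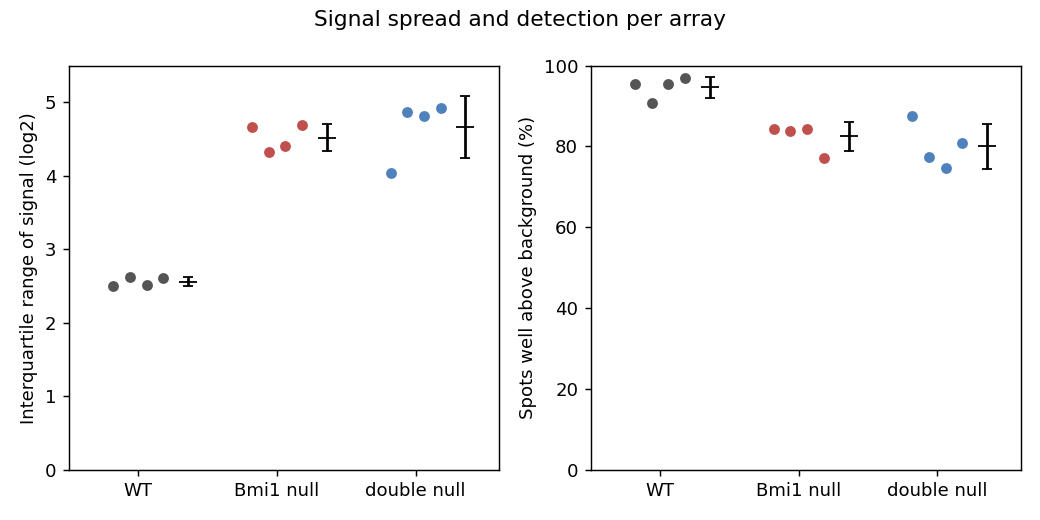
Interquartile range of log2 signal (left, log2 units) and percentage of spots well above background (right) on each array; points are single colonies, bars the mean and SD of 4 colonies. The 4 wild-type arrays lie at 2.49 to 2.62 in range and the 8 mutant arrays at 4.04 to 4.93.

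The comparison of Bmi1 null with wild-type colonies asks which transcripts change when Bmi1 is lost. Hox genes, the classical targets of Polycomb repression, were lower and not higher: of 35 tested, 0 were higher, 33 lower and 2 not called. Genes of squamous (cornified) differentiation were higher, with 25 higher, 4 lower and 7 not called of 36, and so were epithelial markers, with 29 higher, 2 lower and 8 not called of 39. Targets of the tumour suppressor p53 were higher, with 24 higher, 3 lower and 8 not called of 35. Of 30 immune cell markers, 30 were lower, and 869 of 875 olfactory receptor genes were lower too, with a median log2 fold change of -3.54 (747 lower and a median of -1.61 in the authors' processed value table).

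The median log2 fold change of all genes in this comparison was -1.24, and it ranged with the scaling from -1.24 to -0.087, so log2 values of genes and lists against wild type are given from here on relative to the median of all genes. The at-least folds, medians of receptor and ribosomal families and counts of higher and lower genes are those of the fit itself. So are the calls, standard errors and limma adjusted p-values of genes. They test the change before the median was taken off and not the relative value beside them. The largest rises included loricrin (Lor), a main protein of the cornified envelope, at 6.75 ± 1.15 (SE, n = 4 per group, limma adjusted p = 0.000665), the small proline-rich protein Sprr1a at 5.93 ± 0.70 and the epidermal protease Klk14 at 5.92 ± 0.79. The largest falls included those of Olfr1299 (-7.29 ± 0.48) and Olfr1330 (-7.26 ± 0.73), both olfactory receptors well above background on 1 of 4 Bmi1 null arrays, and Speer4d, a testis gene, at -6.71 ± 0.68. Among p53 targets, Cdkn1a, the cell cycle inhibitor p21, rose by 4.58 ± 0.26 (adjusted p = 2.49e-07), Btg2, an antiproliferative gene, by 4.17 ± 0.29 and Ddit4, an inhibitor of mTOR signalling, by 4.11 ± 0.30. All 7 cyclin-dependent kinase inhibitors were called, with 4 higher (Cdkn1a, Cdkn1c, Cdkn2a and Cdkn2b) and 3 lower, among them Cdkn2c at -0.70 ± 0.39. The call of Cdkn2c belongs to its larger fall before the median was taken off. Cdkn2b is named beyond the rule for named genes, after its value had been seen. Of the epithelial markers, Col17a1, a hemidesmosome collagen, reached 4.40 ± 0.29, the junction protein Jup 3.85 ± 0.24 and Trp63, the transcription factor of basal epithelium, 3.81 ± 0.20. The ligand Wnt7b rose by 5.30 ± 0.26 and the BMP target Id1 by 4.96 ± 0.52. The enamel genes Enam and Mmp20 were at least 16.1-fold and at least 5.14-fold lower, being well above background on 0 of 4 Bmi1 null arrays (log2 fold changes of -1.40 and -0.30 in the authors' table). Their list of 21 ameloblast markers had 7 higher, 10 lower and 4 not called and no call as a list (relative median 0.50, camera adjusted p = 0.967). The stem cell marker Lgr5 fell by 1.54 ± 0.41 and Sfrp5, a Wnt antagonist, by 1.35 ± 0.30. The list of 28 stem cell markers had as many higher as lower members, with 11 higher, 11 lower and 6 not called. It was not called as a list (relative median 0.91, camera adjusted p = 0.131). Tyrobp, a signalling adaptor of myeloid cells, fell by 4.12 ± 0.59 and the macrophage marker Adgre1 by 4.11 ± 0.44. In both comparisons with wild type, such rises and falls were not told apart from a difference in the wild-type material. Its arrays had the narrower range of signals and olfactory receptor signal well above background.

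In all, limma called 25935 genes, 7831 higher and 18104 lower (30.2% higher). Median scaling, quantile normalization and the authors' processed value table gave 47.1%, 46.6% and 46.4% higher. The Hox list had a relative median of -1.44 (camera, preset correlation, adjusted p = 0.000157; adjusted p = 0.248 with an estimated correlation), -1.36 with the slide as a block, and -2.74 and -2.63 before the median was taken off within the 2 slides that held both genotypes. The p53 list had 2.92 (adjusted p = 2.33e-09; adjusted p = 0.139 with an estimated correlation), 3.04 with the slide as a block and 1.92 and 1.40 within slides. The squamous list had 3.55 (adjusted p = 2e-06; adjusted p = 0.390 with an estimated correlation), 3.41 with the block and 2.24 and 1.82 within slides. The epithelial list had 2.61 (adjusted p = 5.12e-09; adjusted p = 0.061 with an estimated correlation) and 2.69 with the block, and the immune list -0.84 (adjusted p = 0.00042; adjusted p = 0.390 with an estimated correlation) and -0.84 with the block. In the authors' table the relative medians were -0.99 for Hox, 1.11 for p53, 1.90 for squamous, 0.90 for epithelial and -1.20 for immune genes, all called. Adjusted over the list alone, the counts of these 5 lists were the same. Polycomb subunits rose as a list, with 19 higher, 5 lower and 8 not called of 32 and a relative median of 2.03 (1.23 in the authors' table; adjusted p = 8.59e-05; adjusted p = 0.063 with an estimated correlation), among them Pcgf3 at 3.85 ± 0.31 and Aebp2 at 3.60 ± 0.21. The list of immediate early and stress genes had 18 higher, 8 lower and 5 not called of 31, with a relative median of 1.95 (adjusted p = 0.000413; adjusted p = 0.060 with an estimated correlation). It included the transcription factors Myc at 3.71 ± 0.22 and Klf4 at 3.70 ± 0.35. Its call ended with quantile normalization (0.98) and in the authors' table (1.05).

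The comparison of double null with wild-type colonies asks what remains changed when Ink4a/Arf is lost together with Bmi1. Hox genes were again lower, with 0 higher, 34 lower and 1 not called of 35, and so were all 30 immune cell markers and 874 of 875 olfactory receptor genes (median log2 fold change -3.73; 748 lower and a median of -1.64 in the authors' table). Genes of both proliferative phases were higher: of 48 S phase genes 28 were higher, 8 lower and 12 not called, and of 50 G2/M genes 36 were higher, 4 lower and 10 not called. Epithelial markers were higher, with 32 higher, 4 lower and 3 not called of 39, and p53 targets had 23 higher, 5 lower and 7 not called of 35.

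Relative to a median of all genes of -1.40, the largest rises included those of Tmem14c, a mitochondrial membrane protein of haem synthesis, at 6.01 ± 0.21 (SE, limma adjusted p = 5.89e-09), Ddx3y, a Y-linked RNA helicase, at 5.88 ± 1.14, the imprinted gene Mest at 5.64 ± 0.50 and fibronectin (Fn1) at 5.34 ± 0.41. Olfr1330 was at least 283-fold lower and the class I histocompatibility gene H2-Q1 at least 149-fold lower. Of the S phase genes, Pcna, the sliding clamp of DNA polymerase, reached 3.81 ± 0.30 (adjusted p = 9.14e-06) and thymidine kinase (Tk1) 3.79 ± 0.32. Of the G2/M genes, the mitotic kinase Cdk1 reached 4.09 ± 0.30, with 1 of its 2 probes going the other way, Dlgap5, a spindle protein, 3.80 ± 0.34 and the checkpoint protein Mad2l1 3.67 ± 0.37. Cdkn1a was still higher than in wild type, at 3.59 ± 0.26, as was Ddit4 at 3.34 ± 0.30, while the death receptor Fas fell by 1.17 ± 0.24. The stem cell markers Igfbp5 and Trp63 reached 4.39 ± 0.60 and 4.03 ± 0.20, and the cell adhesion genes Cldn7, Epcam and Cldn1 reached 4.40 ± 0.31, 4.17 ± 0.34 and 4.09 ± 0.25. Smo, the signal transducer of the Hedgehog pathway, reached 3.92 ± 0.27, while its list of 16 genes had 4 higher, 8 lower and 4 not called and no call as a list (camera adjusted p = 0.862). Within the squamous list, Sprr1a rose by 4.10 ± 0.70 (1.91 and not called in the authors' table) while involucrin (Ivl) and Sprr2d fell by 1.32 ± 0.37 and 2.09 ± 0.24.

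With the slide as a block the calls of Ddx3y (4.31), Igfbp5 (3.90) and Sprr1a (2.93) ended. Limma called 26548 genes here, 7937 higher and 18611 lower (29.9% higher; 46.4% with median scaling, 46.5% with quantile normalization and 46.4% in the authors' table). The Hox list had a relative median of -1.84 (camera adjusted p = 0.000121; adjusted p = 0.247 with an estimated correlation), -1.57 with the slide as a block, and -3.12 before the median was taken off within the 1 slide that held both genotypes. Relative medians were 2.33 for S phase (adjusted p = 2e-06; adjusted p = 0.373 with an estimated correlation) and 2.47 for G2/M (adjusted p = 7.04e-09; adjusted p = 0.363 with an estimated correlation). They were 2.93 for epithelial markers (adjusted p = 2.22e-09; adjusted p = 0.061 with an estimated correlation), -0.89 for immune markers (adjusted p = 0.0005; adjusted p = 0.390 with an estimated correlation) and 2.19 for p53 targets (adjusted p = 3.29e-05; adjusted p = 0.289 with an estimated correlation). With the slide as a block these 5 were 2.64, 2.67, 2.92, -0.84 and 2.37. In the authors' table the relative medians were -0.96 for Hox, 1.22 for S phase, 1.30 for G2/M, 1.08 for epithelial and -1.27 for immune genes, all called. Within the shared slide, before the median was taken off, S phase, G2/M and p53 targets had 1.08, 1.25 and 0.74. Adjusted over the list alone, 35 Hox genes and 4 p53 targets were lower and 13 squamous genes higher, and the other counts of these lists were the same. The list of stem cell markers had 14 higher, 8 lower and 6 not called of 28, with a relative median of 2.08 (adjusted p = 0.00699; adjusted p = 0.074 with an estimated correlation), and was not called with the filter on all 12 arrays (1.27, adjusted p = 0.110); in the authors' table it lay at 0.82. The squamous list had 14 higher, 4 lower and 18 not called of 36, with a relative median of 2.38 (adjusted p = 0.0005; adjusted p = 0.549 with an estimated correlation), 2.14 with the slide as a block and -0.34 within the shared slide before the median was taken off. With quantile normalization and in the authors' table the p53 list (0.67 and 0.45) and the squamous list (1.18 and 1.07) were not called.

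Both mutants moved largely together against wild type. Of the genes called in both comparisons, 6933 were higher in both and 17222 lower in both, where independent lists would share 2001 and 10846, and 78 and 53 went opposite ways. The fold changes correlated at r = 0.954 over genes, which are not independent replicates, with a covariance of 4.23. Unchanged groups sharing the same wild-type arrays gave r = 0.501 and a covariance of 0.062 in 100 simulations. When each comparison used a different pair of wild-type arrays, r was 0.932 to 0.949 and 21788 to 22453 genes went the same way. The simulations and these splits address only the noise of shared arrays. All wild-type arrays had the narrower range of signals, so neither can separate a shared effect of genotype from a difference in the wild-type material.

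The comparison of double null with Bmi1 null colonies asks which transcripts depend on Ink4a/Arf once Bmi1 is absent. Cell cycle genes were higher in double null colonies: of 48 S phase genes 23 were higher, 0 lower and 25 not called, and of 50 G2/M genes 29 were higher, 1 lower and 20 not called. Targets of p53 were lower, with 0 higher, 15 lower and 20 not called of 35. Cdkn2a, Cdkn1c and Cdkn1a, all inhibitors of cyclin-dependent kinases, were lower, and the stem cell markers Igfbp5, Lgr5 and Lrig1 were higher. The mutants also differed in sex-linked transcripts: Xist, transcribed from the inactive X chromosome, fell by 7.57 ± 1.22 (SE), being well above background on 1 of 4 double null arrays, and the Y-linked genes Ddx3y, Uty and Kdm5d were at least 57.3-fold, 16.3-fold and 13.4-fold higher in double null colonies. In the authors' table the log2 fold changes of Ddx3y, Uty and Kdm5d were 3.95, 2.20 and 2.14, smaller than these bounds of the main fit.

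Of the S phase genes, E2f2, a transcription factor of the G1/S transition, rose by 1.67 ± 0.26 on the log2 scale (n = 4 per group, limma adjusted p = 0.00299), Clspn, a checkpoint adaptor, by 1.64 ± 0.36 (adjusted p = 0.0167) and Tk1 by 1.60 ± 0.32 (adjusted p = 0.0102). Of the G2/M genes, the mitotic kinase Pbk rose by 2.35 ± 0.34 (adjusted p = 0.00197) and Racgap1, a component of the central spindle, by 1.85 ± 0.30 (adjusted p = 0.00388), whereas Gtse1, which restrains p53, fell by 1.81 ± 0.38 (adjusted p = 0.0124). The S phase list had a median of 0.87 (camera adjusted p = 5.23e-22; adjusted p = 0.083 with an estimated correlation) and 35 higher members adjusted over the list alone. The G2/M list had a median of 1.08 (adjusted p = 2.1e-26; adjusted p = 0.099 with an estimated correlation), with 38 higher and 1 lower over the list alone. Fry, which tests a list by itself and not against all other genes, called both (fry adjusted p = 0.000248 for S phase and 0.000452 for G2/M). The mean S phase level was higher on every double null array than on every Bmi1 null array, and so was the G2/M level.

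Among p53 targets, Psrc1, a spindle protein, fell by 1.62 ± 0.19 (adjusted p = 0.000609), Mdm2, the ligase that degrades p53, by 1.60 ± 0.29 (adjusted p = 0.00613) and Trp53inp1, a proapoptotic cofactor of p53, by 1.47 ± 0.30 (adjusted p = 0.0106). Cdkn1a fell by 1.16 ± 0.26 (adjusted p = 0.0188), a call that ended without replicate 2 (-1.04) or 3 (-1.12) of the double null. It also ended with the slide (-1.36, adjusted p = 0.0687) or the replicate number (-1.16, adjusted p = 0.0616) as a fixed block and with array weights (-1.18). Cdkn1c, an imprinted inhibitor of the cell cycle, fell by 2.13 ± 0.33 (adjusted p = 0.00284). The p53 list had a median of -0.94 (camera adjusted p = 3.76e-10; adjusted p = 0.118 with an estimated correlation), with 23 lower members adjusted over the list alone. Fry called the p53 list too (fry adjusted p = 0.000151). The list of 7 cyclin-dependent kinase inhibitors had 0 higher, 3 lower and 4 not called (1 higher and 3 lower adjusted over the list alone) and no call as a list (camera adjusted p = 0.170).

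**Figure D3:**
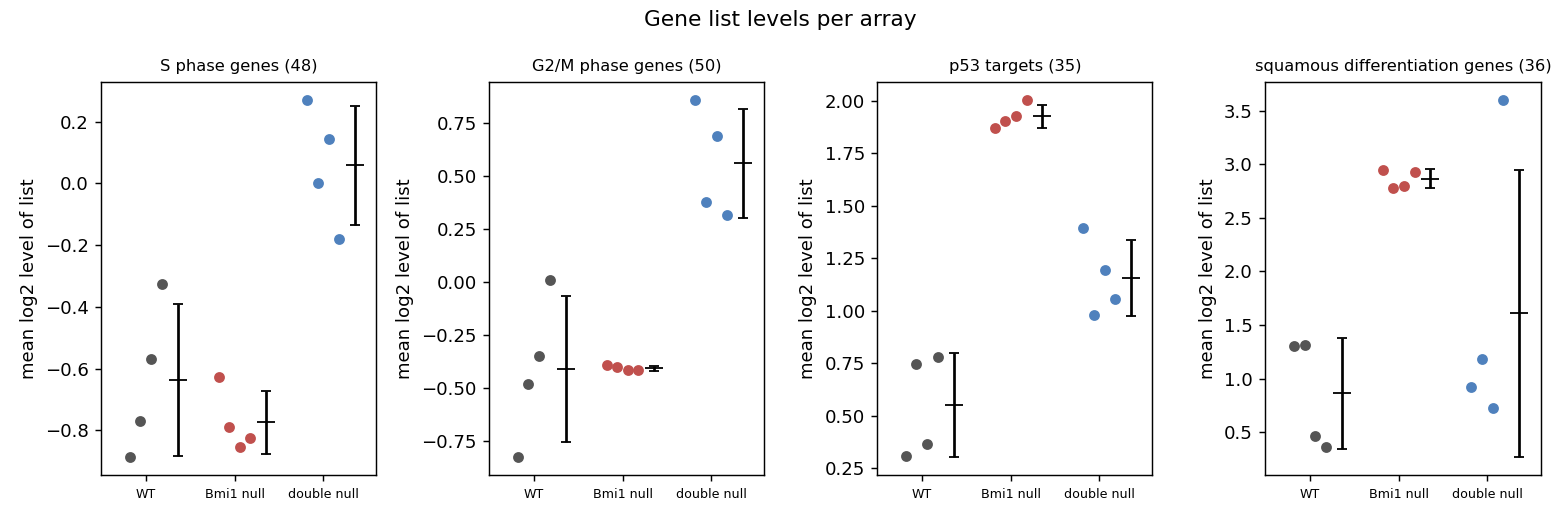
Mean log2 level of 4 gene lists on each array (vertical axis: log2 signal minus the array's 75th percentile, averaged over the members given in parentheses; points: single colonies; bars: mean and SD of 4 colonies). S phase levels are -0.18 to 0.27 on double null and -0.85 to -0.63 on Bmi1 null arrays, p53 target levels 0.98 to 1.39 and 1.87 to 2.00, and replicate 4 of the double null stands apart in squamous genes at 3.60.

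The list of dental epithelial stem cell markers had 5 higher, 0 lower and 23 not called of 28, with a median of 0.057 (0.014 to 0.15 without single arrays; camera adjusted p = 0.00737; adjusted p = 0.074 with an estimated correlation). Igfbp5, a secreted modulator of insulin-like growth factors, rose by 4.91 ± 0.60 (adjusted p = 0.000794), Lgr5, a receptor of Wnt-responsive stem cells, by 1.91 ± 0.41 (adjusted p = 0.0146) and Lrig1, a brake on growth factor receptors, by 1.92 ± 0.42 (adjusted p = 0.0163). The other 2, Etv5 and Sox21, are named after their values had been seen. The calls of Lgr5 and Lrig1 ended with only the 2 genotypes compared (adjusted p = 0.0718 and 0.0776) and with the slide as a fixed block (1.58 and 1.59). The call of Igfbp5 ended with the slide block (4.48), that of Lrig1 also without replicate 3 of the double null (1.72), and that of the list with normexp (0.20). Epithelial markers had 4 higher, 2 lower and 33 not called of 39 and no call as a list (adjusted p = 0.246). The claudin Cldn7 rose by 3.57 ± 0.31 (adjusted p = 7.41e-05) and Epcam by 1.72 ± 0.34, and the keratin Krt7 fell by 2.09 ± 0.36. In the list of Hedgehog pathway genes, 3 members were higher (Hhip, Gas1 and Cdon, receptors or antagonists of the pathway's ligands), 0 lower and 13 not called of 16. Its median was 0.13 (adjusted p = 0.0492; adjusted p = 0.247 with an estimated correlation), and the call ended in 17 of 28 alternatives, the median turning to -0.029 without replicate 4 of the Bmi1 null. The call of Gas1 also ended without that array (1.42), with only the 2 genotypes compared and with the slide (1.49) or the replicate number as a fixed block.

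Of the squamous differentiation genes, 0 were higher, 4 lower and 32 not called of 36 in double null against Bmi1 null colonies (1 higher and 8 lower adjusted over the list alone). The list median was -0.74 (camera adjusted p = 0.00368; adjusted p = 0.625 with an estimated correlation; fry adjusted p = 0.163). Cdsn, an adhesion protein of cornified cells, fell by 3.71 ± 0.68 (adjusted p = 0.00676), Lor by 4.26 ± 1.15 (adjusted p = 0.0416) and the protease Klk7 by 3.68 ± 1.02 (adjusted p = 0.0476). The fourth, Sprr1b, is named after its value had been seen. Replicate 4 of the double null had a squamous level of 3.60, against 0.73 to 1.18 in the other 3 colonies of that genotype. Without it the list median was -1.49, and without replicate 1 it was -0.37 and not called (adjusted p = 0.186). The calls of Lor and Klk7 ended when any array but replicate 4 of the double null was left out (-3.28 and -3.10 without replicate 3 of the double null). Mesenchymal markers had 5 higher, 1 lower and 36 not called of 42, with a median of 0.13 (adjusted p = 0.0261; adjusted p = 0.474 with an estimated correlation), among them the smooth muscle gene Tagln at 2.13 ± 0.35, with 1 of its 2 probes going the other way. The list was not called with the slide as a fixed block (0.043, adjusted p = 0.541) or with normexp (0.47, adjusted p = 0.403). Its call also ended with the filter on all 12 arrays, with only the 2 genotypes compared, in the authors' table (0.068), or without replicate 4 of the double null (0.20) or of the Bmi1 null (0.032).

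The largest other rises included those of the eosinophil chemokine Ccl11 (at least 18.2-fold), the retinol carrier Rbp4 at 4.90 ± 0.76, the vessel growth factor Angpt1 at 4.41 ± 0.39 and the Hedgehog antagonist Hhip at 3.86 ± 0.62. Rbp4 and Hhip were well above background on 2 of 4 and Angpt1 on 3 of 4 Bmi1 null arrays. The largest other falls included those of the xenobiotic-metabolising enzymes Cyp1a1 (at least 12.6-fold, with no call under normexp at -1.38) and Nqo1 (-4.68 ± 0.46, adjusted p = 0.000159), the retinoic acid-producing enzyme Aldh1a1 (-4.54 ± 0.38, adjusted p = 5.29e-05), Lyg1, a lysozyme-like protein, at -4.37 ± 0.78, the potassium channel Kcnj15 at -4.01 ± 0.32 and Sp110, a nuclear body protein well above background on 2 of 4 double null arrays, at -3.99 ± 0.50. In the authors' table the log2 fold changes of Ccl11 and Cyp1a1 were 2.42 and -2.35, smaller than their bounds here. The BMP targets Id1 and Id4 went opposite ways, at -3.0 ± 0.52 and 2.10 ± 0.44, and the ligands Wnt10a and Wnt4 fell by 2.65 ± 0.44 and 1.32 ± 0.20. Of 35 Hox genes, Hoxa5 was at least 2.38-fold higher, well above background on 3 of 4 double null arrays, Hoxc8 was called but not well above background on any array of either mutant, and 33 were not called (list median -0.30, adjusted p = 0.294). The call of Hoxa5 ended without replicate 4 of the Bmi1 null (2.00) or replicate 2 (1.99) or 3 (1.82) of the double null. It also ended with normexp (0.91), with the floor (1.28), with only the 2 genotypes compared (adjusted p = 0.0745) and with the slide as a fixed block (1.96, adjusted p = 0.173).

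Limma called 2343 genes, 848 higher and 1495 lower (36.2% higher; 46.7% with median scaling, 48.6% in the authors' table and 56.5% with normexp), and 6805 had an unadjusted p under 0.05. The median of all genes was -0.073, and 0.25 with normexp, which left 0.50 for the S phase list and 0.66 for the G2/M list relative to it, against 0.95 and 1.15. With the slide as a fixed block 302 genes were called, 287 of them among the 2343, with list medians of 0.96 for S phase, 1.09 for G2/M, -0.94 for p53 targets and -0.98 for squamous genes, all 4 called by camera, while 26 of the 45 genes that the rule let the text name here lost their call. Within the 2 slides that held both mutants, the S phase median was 0.95 and 0.88, the G2/M median 1.18 and 1.04, the p53 median -0.68 and -0.95 and the squamous median -1.14 and -0.48. All 4 Bmi1 null colonies had high Xist and no Ddx3y or Kdm5d signal well above background, and all 4 double null colonies had both Ddx3y and Kdm5d well above background, so these markers of sex went together with genotype. The Y-linked probes of Eif2s3y and Ssty1 were well above background on 3 of 4 Bmi1 null arrays too, at signals of 16.4 to 55.4. Of the called genes with a known chromosome, 53 of 1287 lay on X or Y. The share of X and Y among all tested genes was not set beside this, and it does not measure effects of sex on autosomal genes. The count of 2343 called genes was 1508 without replicate 4 of the Bmi1 null and 1436 without replicate 3 of the double null.

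**Figure D4:**
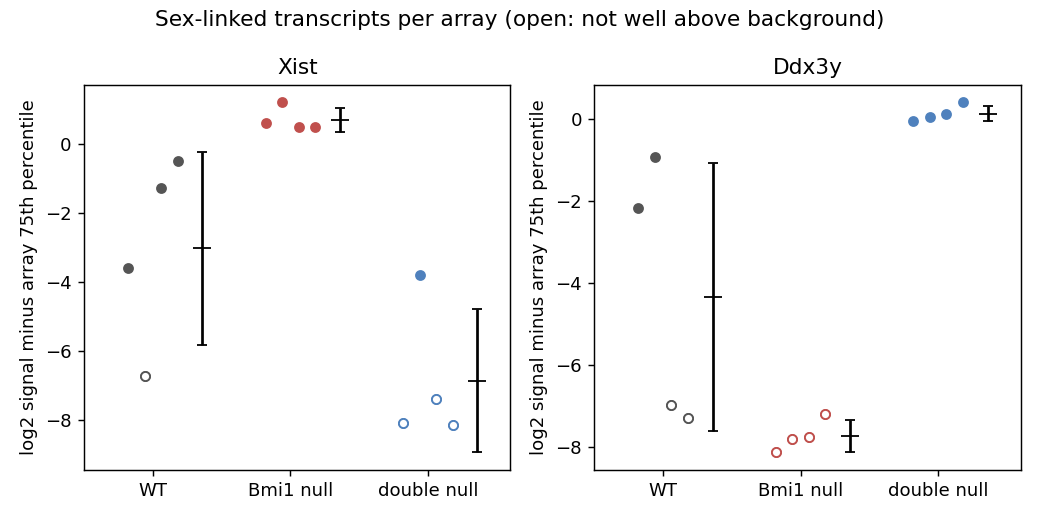
Levels of Xist (left) and the Y-linked gene Ddx3y (right) on each array (vertical axis: log2 signal minus the array's 75th percentile; points: single colonies, open where not well above background; bars: mean and SD of 4 colonies). Ddx3y is well above background on 4 of 4 double null, 2 of 4 wild-type and 0 of 4 Bmi1 null arrays.

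Of the genes called in Bmi1 null against wild-type colonies, 930 went the opposite way in double null against Bmi1 null colonies: 545 higher and then lower, and 385 lower and then higher, where independent lists would share 377 and 494. Another 171 were higher and 521 lower in both comparisons, where independent lists would share 214 and 871. The fold changes correlated at r = -0.073 over genes with a covariance of -0.097, beside -0.50 and -0.062 for unchanged groups sharing the same Bmi1 null arrays. When each comparison used a different pair of Bmi1 null arrays, r was -0.10 to 0.09, and 253 to 553 genes went opposite ways and 100 to 614 the same way. More went the same way in 3 of 6 splits, so the excess of opposite changes did not hold in every split without shared arrays. The count of 930 was 140 with the slide as a block, 572 without replicate 4 of the Bmi1 null and 616 without replicate 3 of the double null.

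No difference in the share of called genes was detected between genes near the targeted loci and others. Within 20 Mb of Bmi1 on chromosome 2, 80.5% of 353 genes were called in Bmi1 null against wild-type colonies, against 83.2% of the other genes (two-sided Fisher's exact test, p = 0.173). In double null against wild-type colonies the shares were 81.6% and 84.1% (Fisher's exact test, p = 0.211), and between the mutants 9.35% and 7.54% (p = 0.221). Within 20 Mb of Cdkn2a on chromosome 4, the shares among 141 genes were 83.0% against 83.1% (Fisher's exact test, p = 0.910), 87.2% against 84.1% (p = 0.355) and 8.51% against 7.56% (p = 0.631). All 6 adjusted p-values were 0.443 or more.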

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

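Each value below lay far from the other 3 arrays of its genotype by Dixon's test of a gap against the range. It was met by 24 of 263 groups of 4 arrays, or 9.13%, where chance gives about 1 in 20. All of these tests were chosen before the data were examined except for the choice of genes, which followed the values. Gene values are log2 signal minus the array's 75th percentile.

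Among measures of whole arrays, 77.2% of spots were well above background on replicate 4 of the Bmi1 null, against 83.8% to 84.4% on the others. The log2 interquartile range of replicate 1 of the double null was 4.04, against 4.81 to 4.93. The median signal of wild-type replicate 5 was 210, against 109 to 125. Replicate 1 of the double null had 1336 spots marked by the scanner software as outliers, against 74 to 102. The mean level of squamous differentiation genes was 3.60 on replicate 4 of the double null, against 0.73 to 1.18. The mean level of interferon-stimulated genes was -1.95 on replicate 1 of the double null, against -2.45 to -2.38.

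Among genes on Bmi1 null arrays, Bmi1 lay at -2.13 and Epcam at 2.00 on replicate 4, and Olfr1299 at -4.78, Olfr1330 at -2.94, Speer4d at -0.12, Cdkn2c at -0.97 and Xist at 1.22 on replicate 2. On wild-type arrays, Cdkn2a lay at -5.79, Olfr1330 at 2.92 and Tyrobp at 1.73 on replicate 3, and Sfrp5 at -1.77 and Aebp2 at -1.36 on replicate 5. On double null arrays, Klk7 lay at 5.14, Tagln at 4.21 and Lyg1 at 1.25 on replicate 4, Dlgap5 at 0.65 and Kcnj15 at -0.52 on replicate 1, and Tmem14c at 3.98 on replicate 3.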

How the results depend on the processing

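The slide as a random block and the count on autosomes were chosen only after the result was seen. Against wild type both counts of called genes stayed within 1.5 times under all alternatives run (24824 to 26090 and 25603 to 26643 without single arrays). Between the mutants the count of 2343 was 1461 with normexp, 1367 with quantile normalization, 968 with only the 2 genotypes compared, 302 with the slide as a fixed block (2357 as a random one), 1234 on autosomes, where genes of unknown chromosome also drop out, and 1436 to 2695 without single arrays (1508 without replicate 4 of the Bmi1 null). The replicate number as a fixed block gave 25186, 25883 and 1398 calls and as a random one 26014, 26621 and 2487. Deviations of same-numbered arrays correlated at -0.11, 0.06 and 0.14, at 0.13, 0.06 and -0.14, and at -0.12, 0.22, 0.02 and 0.08 in the 3 comparisons, so the numbers were not taken to pair the colonies. Of the genes changed the same way in both mutants, 24155, the count without single arrays was 22985 to 24197. The 930 changed in opposite ways were 427 with only the 2 genotypes compared, 549 with the replicate block, 140 with the slide block and 572 to 1004 without single arrays. The Hox list lay at -1.68 to -1.33, -1.93 to -1.73 and -0.42 to -0.20 without single arrays in the 3 comparisons. The Hedgehog list between the mutants lay at -0.029 to 0.28 without single arrays. Cdkn2a in double null against wild-type colonies reversed from -0.42 to 0.31 with normexp, 0.70 with quantile normalization, 0.72 with the floor and 0.20 in the authors' table. Between the mutants Bmi1 turned to 0.093 with normexp and Hoxc8 to 0.51 with normexp and 0.16 with the floor. For these values the cause was not tested. Those of Cdkn2a and Hoxc8 come from probes not well above background in either genotype, so they show a change of sign between settings and no fold. Of 728 alternatives for lists in each comparison, 696, 692 and 625 kept direction and side of the threshold, 3, 18 and 25 lost a call with their direction kept, 9, 0 and 4 gained one and 20, 18 and 74 changed sign. Only the Hedgehog and sex-linked lists between the mutants had a call to lose there, and the other medians were called in neither fit. Their medians, relative to that of all genes against wild type, are given last with lists named by a short form. Apart from the shift of all genes given there, the cause was not tested for these either. Of the 28, 25 and 45 genes of the rule named in the text, 1, 3 and 28 lost their call somewhere, and 0, 0 and 7 without some array. Signal over background limits the dim genes: probes not well above background in a genotype give bounds only, and 82.5% and 80.1% of spots were well above background on the mutant arrays.

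In Bmi1 null against wild-type colonies, with normexp the mesenchymal list turned to -0.069. With quantile normalization the mesenchymal list turned to -0.37. With the filter on all 12 arrays the mesenchymal list turned to -0.45 and imprinted to -0.037. With the floor the mesenchymal list turned to -0.019. With the mean of probes the ameloblast list turned to -0.34. With every probe the mesenchymal list turned to -0.21. With array weights the mesenchymal list turned to -0.029. With the replicate block the senescence-associated list turned to 0.0051 and Hedgehog to 0.14. With the slide block the mesenchymal list turned to -0.11 and senescence-associated to 0.033. In the authors' table the mesenchymal list turned to -0.36, senescence-associated to 0.014 and imprinted to -0.060. Without single arrays the mesenchymal list lay at -0.10 to 0.14, senescence-associated at -0.30 to 0.011 and Hedgehog at -0.23 to 0.068. In double null against wild-type colonies, with normexp the Hedgehog list turned to -0.0011. With quantile normalization the mesenchymal list turned to -0.015, senescence-associated to -0.21, Hedgehog to -0.81 and imprinted to -0.32. With the filter on all 12 arrays the senescence-associated list turned to -0.25, Hedgehog to -0.14 and sex-linked to -0.92. With the floor the ameloblast list turned to -0.026. With the mean of probes the ameloblast list turned to -0.12. With every probe the ameloblast list turned to -0.15. In the authors' table the ameloblast list turned to -0.0013, Hedgehog to -0.53 and imprinted to -0.45. Without single arrays the ameloblast list lay at -0.19 to 0.19 and mesenchymal at -0.015 to 1.02. Between the mutants, with normexp the Hox list turned to 0.37, Hox cofactors to 0.18, transcription factors to 0.36, kinase inhibitors to -0.021, epithelial to -0.032, ameloblast to 0.26, immune to 0.22, endothelial to 0.38, glial to 0.25, senescence-associated to 0.15, interferon to 0.22, Wnt to 0.30 and imprinted to 0.0091. These medians between the mutants are not relative to that of all genes. The median of all genes was itself -0.073 in the main fit, 0.25 with normexp and 0.034 with median scaling. A turn to a value near it holds that shift of all genes. With quantile normalization the transcription factor list turned to 0.050, epithelial to -0.0052, ameloblast to 0.024, endothelial to 0.11, glial to 0.058 and Wnt to 0.082. With median scaling the Hox cofactor list turned to 0.044, transcription factors to 0.070, ameloblast to 0.083, endothelial to 0.11, glial to 0.030, Wnt to 0.080 and imprinted to 0.0074. With the filter on all 12 arrays the Hox cofactor list turned to 0.060, ameloblast to 0.0058, endothelial to 0.015, Wnt to 0.050 and sex-linked to -0.32. With the floor the transcription factor list turned to 0.0036, ameloblast to 0.070, endothelial to 0.051 and imprinted to 0.042. With the mean of probes the Hox cofactor list turned to 0.15, FGF to -0.0063 and Wnt to 0.037. With every probe the endothelial list turned to 0.032, Wnt to 0.050 and stress to -0.11. With the slide block the Hox cofactor list turned to 0.054, Polycomb to -0.023, epithelial to -0.013 and stress to -0.060. In the authors' table the Hox cofactor list turned to 0.056, transcription factors to 0.00036, immune to 0.020, endothelial to 0.015 and Wnt to 0.035. Without single arrays the Hox cofactor list lay at -0.11 to 0.27, transcription factors at -0.12 to 0.070, kinase inhibitors at -0.13 to 0.11, ameloblast at -0.10 to 0.084, immune at -0.21 to 0.0084, endothelial at -0.18 to 0.17, glial at -0.15 to 0.0093, Hedgehog at -0.029 to 0.28, FGF at -0.11 to 0.10, Wnt at -0.12 to 0.072, imprinted at -0.12 to 0.13 and stress at -0.077 to 0.10.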

Other observations

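Tests of the slide, of scaling, of sex and of the Hox level per array were chosen only after the result was seen, as were the receptor and ribosomal families and a second selection of probes in the test of X-linked signal. The remaining tests were written before their result was known.

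Other gene groups moved against wild type. Of 133 other developmental transcription factors, 12 were higher and 110 lower in Bmi1 null colonies (relative median -0.80, camera adjusted p = 0.00165; adjusted p = 0.388 with an estimated correlation) and 10 higher, 16 not called and the others lower in double null colonies (-0.60, adjusted p = 0.00287; adjusted p = 0.390 with an estimated correlation). Endothelial markers had 1 higher and 17 lower of 18 in both (-0.89, adjusted p = 0.0288, and -0.75, adjusted p = 0.0492; adjusted p = 0.474 and 0.495 with an estimated correlation), with no call in the authors' table. In double null colonies the call ended in 13 alternatives, among them the slide (adjusted p = 0.0539) and the replicate number (0.0528) as a fixed block. Glial, neural and melanocyte markers had 2 higher and 21 lower of 23 in Bmi1 null (-0.81, adjusted p = 0.0173; adjusted p = 0.247 with an estimated correlation) and 1 higher and 20 lower in double null colonies (-0.72, adjusted p = 0.0261; adjusted p = 0.259 with an estimated correlation). Polycomb subunits had 19 higher and 5 lower of 32 in double null colonies (2.07, adjusted p = 1.81e-05; adjusted p = 0.061 with an estimated correlation), and immediate early and stress genes 20 higher and 8 lower of 31 (2.40, adjusted p = 0.000115; adjusted p = 0.060 with an estimated correlation). In the authors' table the glial list lay at -1.17 and -1.29, and in double null colonies the Polycomb list at 1.34 and the stress list at 1.46, all called. In Bmi1 null colonies S phase genes had 14 higher and 17 lower of 48 (adjusted p = 0.148; 20 higher and 9 lower in the authors' table) and G2/M genes 10 higher and 10 lower of 50 (adjusted p = 0.0803), both called with median scaling or with a fixed slide or replicate block. Vomeronasal receptor genes were lower in all 126 tested in both comparisons (medians -3.97 and -4.07; 111 and 109 lower with medians of -1.27 and -1.23 in the authors' table). Of 89 ribosomal protein genes 77 and 78 were higher (medians 1.95 and 2.08; 1.12 and 1.18 in the authors' table).

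A further 9 lists had no call by camera in any comparison. Between the mutants, 0 of 9 Hox cofactors were called (adjusted p = 0.304). Ameloblast markers had 0 higher and 2 lower of 21 (adjusted p = 0.710), senescence-associated secreted factors 3 higher and 3 lower of 43 (adjusted p = 0.885) and interferon-stimulated genes 0 higher and 2 lower of 31 (adjusted p = 0.391). FGF pathway genes had 2 higher and 2 lower of 26 (adjusted p = 0.469), Wnt pathway genes 6 higher and 4 lower of 39 (adjusted p = 0.792), Notch pathway genes 0 higher and 1 lower of 21 (adjusted p = 0.792), BMP and activin pathway genes 1 higher and 2 lower of 31 (adjusted p = 0.567) and imprinted growth genes 1 higher and 1 lower of 19 (adjusted p = 0.944). By contrast, the list of 7 sex-linked genes was called between the mutants, with 4 higher and 1 lower (median 3.73, adjusted p = 0.00084; adjusted p = 0.143 with an estimated correlation).

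The narrow signal range of the wild-type arrays and the many calls against them argue for a difference in the material. On the slide that held 2 wild-type and 2 Bmi1 null arrays, the ranges stood apart by 2.15, which argues against the slide, and 22436 genes were called with quantile normalization, which argues against the scaling. A candidate explanation is template from genomic DNA in the wild-type samples: among probes silent on the mutant arrays, X-linked ones should then lie higher against autosomal ones in colonies without Ddx3y signal well above background (replicates 4 and 5, where the Y-linked probes of Ssty1 and Eif2s3y, and on replicate 4 that of Kdm5d, were still well above background). The X minus autosome median was -1.11 and -1.36 in the wild-type colonies with Ddx3y signal and -0.49 and -0.56 in those without, and the gap of 0.55 met the prediction of more than 0.3 (62 X-linked and 840 autosomal probes; 0.59 with the added selection). The signal of Y-linked Ssty1 was 4463 and 3222 on wild-type replicates 1 and 3, against 3.73 to 20.7 on double null arrays. That of Y-linked Rbmy was 136 and 131, against 1.85 to 23.1. Ddx3y went the other way (56.3 and 154, against 338 to 744), as did Kdm5d and Eif2s3y. These probes were picked after their values had been seen, and the cause was not tested. Changes in abundant transcripts from the genotype stay open beside it, and the levels of dim and of bright genes against wild type may hold both. Among bright genes, those of ribosomal proteins lay 3.81 above the array's own median in wild type, against 6.77 and 7.0 in the mutants. Only the Hox list was set against genes of the same brightness. The rises of other lists against wild type may therefore hold the difference in signal range.

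Hox genes were lower in both mutants against wild type. If this were only the loss of signal that all dim genes showed, the Hox median should lie among those of random lists of genes of the same brightness on the mutant arrays. It lay at percentile 1.09 of 10000 such lists in Bmi1 null colonies (-2.68 against -2.58 to -1.57), and at 0.02 in double null colonies. Such lists take genes as independent, whereas Hox genes correlated at 0.11, where the list lost its call in Bmi1 null colonies (camera adjusted p = 0.248). Per array, which keeps that correlation, the mean Hox level minus that of genes of the same brightness was 0.054 ± 0.23 (SD, n = 4) in Bmi1 null, -0.036 ± 0.059 in double null and 0.81 ± 0.041 in wild-type colonies. Every mutant array lay below every wild-type array (exact permutation test of the means, p = 0.0286 in each comparison, the smallest that 70 permutations can give). Matching on mutant brightness brings the mutant levels close to those of the matched genes by construction. This test also measures the spread between arrays and not between gene lists, so it does not decide the question. The percentiles argue against that explanation alone only where Hox genes are taken as independent. Nor do they set Hox genes apart from receptor families, which were not compared with genes of the same brightness. In Bmi1 null and double null colonies olfactory receptors fell by medians of -3.54 and -3.73 and vomeronasal receptors by -3.97 and -4.07. The Hox medians were smaller, at -2.68 and -3.24. Genomic DNA, with the gap of 0.55 above, may still add to wild-type Hox signal, and whether it adds more to Hox genes than to others was not tested. A loss of Hox transcripts in Bmi1 null cells stays an untested hypothesis.

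Cell cycle genes were higher in double null than in Bmi1 null colonies. The lowest S phase median over 6 scalings was 0.76 and the lowest within a slide 0.88, both of which argue against these as the whole cause. The 0.76 came from normexp, where the list was still called but lay at 0.50 relative to the median of all genes, against 0.95 in the main fit. With an estimated correlation the calls of the S phase and G2/M lists ended (camera adjusted p = 0.083 and 0.099). Fry, which tests a list by itself and not against all other genes, called both (fry adjusted p = 0.000248 and 0.000452). Sex cannot be told apart from genotype here: wild-type colonies with Ddx3y signal lay at -0.38 against those without in S phase level, but wild-type signals are compressed, so this decides nothing. The change may follow from the loss of Ink4a/Arf, as a hypothesis that these colonies cannot separate from the sex of the animals. Nor can they separate it from differences between single animals, since the number of animals behind each genotype is not known.

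Other splits of the 8 arrays of each comparison into 4 and 4 were tried. Of 35 splits, only 1, the real split, gave as many called genes in each of the 3 comparisons. The highest of the others called 0, 0 and 14 genes, against 25935, 26548 and 2343. Every other split put arrays of both genotypes on each side, so any difference between the groups added to the spread within its sides. A share of 1 of 35 is also the smallest that these splits can give. The low counts therefore do not measure how far chance assignment is excluded. Nor do they tell genotype apart from the wild-type material, the sex of the animals or differences between single animals.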
